A study of Mus musculus with 12 samples.

How the data were processed

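The samples are RNA-seq libraries of astrocytes sorted from the cortex and hippocampus of CD51-Flp reporter mice, 3 libraries in each of 4 groups (cortex or hippocampus, labelled CD51+ or CD51−). Per the labels' protocols, RNA was extracted from sorted cells with a column kit, libraries were made from 10 ng of RNA with a low-input kit, and paired-end reads of 150 bases were sequenced on a NovaSeq X Plus. Per the file headers, the deposited values are raw counts: featureCounts 2.0.4 counted read pairs over the exons of each gene of GENCODE vM25, unstranded, with primary alignments only and without pairs on different chromosomes. Per the submitters' processing notes, STAR, the mm10 genome and DESeq2 1.40.2 were used. Because counting was unstranded, genes that overlap on opposite strands cannot be separated.

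Groups follow the sample titles. The library names read G for titles CD51+ and GT for titles CD51−, which could point to the opposite classes. Gene symbols came from a GENCODE vM21 name table, in which 55141 of the 55401 gene IDs of the counts were found, and coordinates came from the counts file. Total counts were 4.35e6 to 12.85e6 per library, and a count of 3 over a group is the floor used for genes with no count in a group. Genes were kept with filterByExpr of edgeR by group (minimum count 10, minimum total 15), which left 12613.

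The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM factors, robust off, all 12 libraries in 1 fit with 4 group levels, and Benjamini-Hochberg adjustment at 0.05. The common dispersion was 1.64, a biological coefficient of variation of 1.28. There were 5 contrasts: CD51+ against CD51− in cortex, in hippocampus and averaged over both, hippocampus against cortex averaged over the classes, and the interaction. CPM values (counts scaled to 1e6 per library) use TMM-scaled library sizes and are given as mean ± SD, and log2 fold changes as estimate ± SE. This SE is the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. For genes with no count in a group no fitted fold is given but a floor, and for genes with 1 to 3 counts a ratio with a 95% counting interval. Itgav was also tested by exact permutation of the libraries within a region.

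Fixed gene lists were tested against all other genes with camera of limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a contrast. There were 32 lists, of which 30 had at least 3 tested members: pan-astrocyte, upper-layer and protoplasmic, and fibrous and pial markers, other integrin subunits, alpha-v ligands and TGF-beta activation, synapse-organising factors, neurotransmitter genes, ion channel genes, matrix genes, reactive genes, cholesterol genes, glycolysis genes, nuclear oxidative phosphorylation genes, mitochondrial mRNAs, ribosomal proteins, proliferation, neural stem genes, immediate early genes, interferon response, Notch, hedgehog, BMP and Wnt genes, patterning factors, and markers of neurons, oligodendrocytes and their precursors, microglia, other leukocytes, endothelium, pericytes, fibroblasts and ependyma or choroid plexus. The words "adjusted over the list alone" mean edgeR p-values adjusted among the members of a list.

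Groups, tests, filters, lists, most alternatives and the rule for naming genes were fixed before the data were examined. The rule names Itgav, then up to 10 higher and 10 lower genes per contrast with the largest absolute log2 fold change among those with an adjusted p under 0.05, at least 5 CPM in the higher group and libraries that do not overlap, leaving out predicted genes, pseudogenes and immunoglobulin segments. It then names up to 4 members of each list by p. The text takes them in that order and leaves some out, and a few of the genes the rule names are not reported here. With 3 against 3 libraries, 10% of genes do not overlap by chance. Here 31.7% did not in cortex and 27.1% in hippocampus.

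The alternatives were DESeq2 1.42.0, limma-voom, RLE factors, upper-quartile scaling, no filter, a stricter filter (1 CPM in 3 libraries), robust dispersion, an absolute log2 fold change of at least 1, a replicate block, a block within each stratum, only the libraries of a region, each library left out, an estimated correlation and fry. Chosen after seeing the data were the fits with mitochondrial genes left out and, for the lists, upper-quartile scaling and left-out libraries, the last also for the shared calls. The edgeR test was tested on simulated data of 12613 genes: at 4 log2 units it recovered 18% of changes in cortex, 22% in hippocampus, 56% in the average and 42% between regions. Between 2.94% and 8.33% of its calls were false. The simulated counts were drawn from the model that edgeR fits, with 50 changed genes of each size. The real data can depart from both, so these shares need not hold there. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Reads of the reporter transgenes were not analysed here.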

Results

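RNA was measured in astrocytes sorted by flow cytometry from the cortex and the hippocampus of reporter mice. In these mice a Flp recombinase under control of CD51, the integrin alpha-v protein encoded by Itgav, switches on tdTomato. What drives GFP in the sorted cells is not given in the sources used here. The labels separate cells called CD51+ (tdTomato and GFP) from cells called CD51− (GFP without tdTomato). The library names could point to the opposite classes, in which case every CD51 difference below would change sign. Each of the 4 groups had 3 libraries, 12 in all. Total counts, in 1e6 read pairs, were 5.5 to 12.85 in cortex CD51+, 7.09 to 8.54 in cortex CD51−, 4.35 to 9.46 in hippocampus CD51+ and 7.25 to 8.59 in hippocampus CD51−. Between 12113 and 15425 genes had at least 1 count. Mitochondrial genes took 36.5%, 47.7% and 71.1% of the counts in the cortex CD51+ libraries and 22.5%, 23.6% and 38.6% in the cortex CD51− libraries. In hippocampus the shares were 49.9%, 52.2% and 53.3% in CD51+ and 26.6%, 29.4% and 20.2% in CD51−. In cortex CD51+ replicate 3 the mitochondrial ribosomal RNAs alone took 58.4% of the counts, against 1.04% to 3.54% in the other libraries. The first principal component, with 31.8% of the variance, placed all 6 CD51+ libraries between -140.1 and -110.5 and all 6 CD51− libraries between 68.9 and 200.6. The labels do not say that the replicates came from separate animals, so the p-values measure the spread between these samples, which can be technical.

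Itgav, the gene of CD51 itself (ENSMUSG00000027087.11, chromosome 2, 83724397 to 83806916 in mm10, plus strand), was detected in every library and did not separate the labelled classes. In cortex it was at 337, 537 and 879 CPM (counts scaled to 1e6 per library) in the CD51+ libraries, a mean of 584 ± 274 (SD, n = 3), and at 358, 248 and 326 CPM in the CD51− libraries, a mean of 311 ± 56.7 (SD, n = 3). In hippocampus it was at 373, 323 and 412 CPM in CD51+, a mean of 369 ± 44.4 (SD, n = 3), and at 223, 565 and 356 CPM in CD51−, a mean of 381 ± 172 (SD, n = 3). The log2 fold change was 0.91 ± 0.55 (SE) in cortex, with an edgeR quasi-likelihood adjusted p of 0.269, and -0.04 ± 0.55 in hippocampus, with an adjusted p of 0.984. An exact two-sided permutation test gave p = 0.2 in cortex and p = 0.9 in hippocampus, where 3 against 3 libraries cannot give a p under 0.1. Averaged over both regions the log2 fold change was 0.43 ± 0.39 (SE; edgeR adjusted p = 0.464). Reads from the tdTomato and GFP transgenes were not analysed here.

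**Figure D1:**
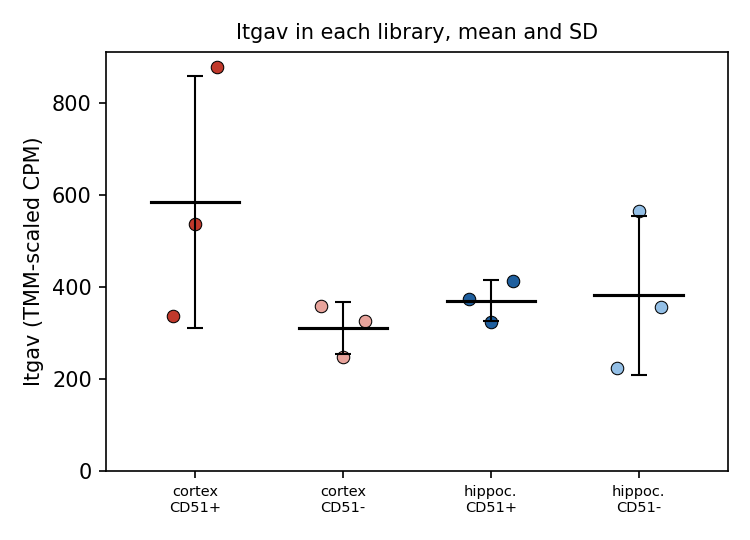
Itgav in each of the 12 libraries in TMM-scaled CPM, with 3 points per labelled group, a line at the mean and a bar for the SD. The classes overlap in both regions, with CD51+ at 337 to 879 and CD51− at 248 to 358 in cortex, and at 323 to 412 and 223 to 565 in hippocampus.

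The first comparison asked how the cortical libraries labelled CD51+ differ from those labelled CD51−. Astrocyte genes were higher in the libraries labelled CD51+. The glutamate transporter gene Slc1a2 (ENSMUSG00000005089.15, chromosome 2, 102658659 to 102790784) stood at 39800 ± 6710 CPM (SD, n = 3) against 4530 ± 3220, a log2 fold change of 3.13 ± 0.39 (SE; edgeR adjusted p = 3.41e-05). Slc1a3, the other astroglial glutamate transporter, was at 4940 ± 687 against 590 ± 269 CPM. In all, 16 of 20 pan-astrocyte markers were higher (18 adjusted over the list alone), with a median log2 fold change of 3.03. The same libraries differed in markers of other cell types: the 14 microglial markers summed to 638 ± 377 CPM (SD, n = 3) in CD51+ and 11630 ± 1780 in CD51−, and the oligodendrocyte markers to 2816 ± 82.6 and 43780 ± 17600 CPM. The pan-astrocyte markers summed to 80720 ± 12000 and 11430 ± 6060 CPM. In CD51− the oligodendrocyte sum thus exceeded the pan-astrocyte sum, and whether genes differed within astrocytes stays open. The limma-voom alternative ended the call of Slc1a2 (adjusted p = 0.733), among 18 alternatives whose adjusted p ran from 1.45e-28 to 0.733. Of the 20 pan-astrocyte markers limma-voom called 17, against 16 in edgeR.

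Genes of astrocyte function in cortex moved with the general markers. Of 24 tested genes of neurotransmitter uptake and reception, 11 were higher and 1 was lower (16 and 1 adjusted over the list alone), with a median log2 fold change of 2.93. Of 17 synapse-organising factors, 7 were higher (11 higher and 1 lower adjusted over the list alone; median 2.99), among them the secreted matricellular protein gene Sparcl1 (15100 ± 1930 against 1610 ± 759 CPM; SD, n = 3). Upper-layer and protoplasmic markers were higher in 4 of 10 cases (9 adjusted over the list alone; median 2.98), among them the GABA transporter Slc6a11 at 922 ± 150 against 43.5 ± 48.2 CPM. Among ion channel, water and calcium genes 8 of 24 were higher and 1 was lower (10 and 1 adjusted over the list alone; median 1.97), and the water channel Aqp4 was at 2180 ± 261 against 246 ± 148 CPM. Camera, the limma test of a list against all other genes, gave adjusted p = 1.57e-14 for the pan-astrocyte list, 6.98e-09 for neurotransmitter genes, 4.58e-05 for synapse factors and 1.13e-06 for upper-layer markers. These 4 lists kept adjusted p = 0.0484, 0.00921, 0.0315 and 0.0315 with an estimated correlation between genes. The ion channel list had a camera adjusted p of 0.000398, and adjusted p = 0.0519 with an estimated correlation.

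No list median in this paragraph exceeded that of the pan-astrocyte markers in cortex, so none shows a rise beyond the general one of astrocyte genes. Cholesterol synthesis and lipoprotein genes were higher in 9 of 24 cases (12 higher and 1 lower adjusted over the list alone; median log2 fold change 2.85). The apolipoprotein gene Apoe was at 3080 ± 375 CPM (SD, n = 3) against 406 ± 248, and the sterol dehydrogenase Nsdhl at 46.3 ± 23.6 CPM against no count, at least 387-fold higher. The camera adjusted p of this list was 1.84e-07, and adjusted p = 0.00414 with an estimated correlation. Of 22 genes of Notch, sonic hedgehog, BMP and Wnt signalling, 6 were higher (9 higher and 1 lower adjusted over the list alone; median 2.37; camera adjusted p = 3.48e-05, and adjusted p = 0.00921 with an estimated correlation). The hedgehog effector Gli2 was at 129 ± 148 CPM in CD51+ with 3 counts in all of CD51−, a ratio of 991 (95% counting interval 338 to 4810). Glycolysis and lactate genes were higher in 6 and lower in 2 of 23 cases (7 and 2 adjusted over the list alone; median 1.43), with the aldolase Aldoc at 5420 ± 1050 against 790 ± 721 CPM. The glycolysis list had a camera adjusted p of 0.00611, and adjusted p = 0.157 with an estimated correlation. Extracellular matrix genes were higher in 5 and lower in 1 of 21 cases (5 and 1 adjusted over the list alone; median 2.68), with the laminin chain Lama2 at 181 ± 41.5 against 6.09 ± 3.77 CPM. For matrix genes camera gave adjusted p = 0.00661, and adjusted p = 0.176 with an estimated correlation. Telencephalic patterning factors were split, with 6 higher and 2 lower of 18 (8 and 3 adjusted over the list alone; median 1.85; camera adjusted p = 0.00491, and adjusted p = 0.157 with an estimated correlation). The homeobox gene Prox1 was lower, with 1 count in CD51+ and 209 ± 285 CPM in CD51−, a ratio of 3550 (95% counting interval 637 to 140000), and the homeobox gene Lhx2 was higher, at 130 ± 53 against 4.45 ± 3.4 CPM. Nuclear genes of oxidative phosphorylation had a median of 1.47 with 1 of 29 higher (1 adjusted over the list alone), the ATP synthase subunit Atp5b at 481 ± 299 against 76.6 ± 42.6 CPM. For this list camera gave adjusted p = 0.000812, and adjusted p = 0.0573 with an estimated correlation. The 13 mitochondrially encoded mRNAs had a median of 0.96 with 2 higher (2 adjusted over the list alone; camera adjusted p = 0.0227, and adjusted p = 0.471 with an estimated correlation; fry 0.0522). The edgeR call of Atp5b ended without cortex CD51+ replicate 2 (adjusted p = 0.099), CD51− replicate 1 (0.0551) or CD51− replicate 2 (0.0787). The camera call of the mitochondrial list ended without cortex CD51+ replicate 2 (adjusted p = 0.106) or CD51− replicate 1 (0.179).

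Immediate early genes, which are transcribed within minutes of stimulation and also during tissue dissociation, were lower in cortex libraries labelled CD51+. The zinc finger factor Egr1 (ENSMUSG00000038418.7, chromosome 18, 34859823 to 34864984) stood at 30.5 ± 17.5 CPM (SD, n = 3) in CD51+ against 6550 ± 1330 in CD51−, a log2 fold change of -7.75 ± 0.65 (SE; edgeR adjusted p = 2.67e-07). Fosb was at 0.822 ± 0.582 against 548 ± 328 CPM, Jun at 22.8 ± 24.8 against 2030 ± 274 CPM and the stress factor Atf3 at 5.67 ± 8.27 against 1430 ± 150 CPM. Of 19 tested members 17 were lower (17 adjusted over the list alone), with a median log2 fold change of -7.75 and a camera adjusted p of 3.12e-23, and adjusted p = 0.00414 with an estimated correlation. The limma-voom alternative ended the call of Egr1 (adjusted p = 0.0868), whose adjusted p over its alternatives ran from 8.38e-47 to 0.0868. Of the 19 members limma-voom called 16, against 17 in edgeR.

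Genes of microglia, other leukocytes and oligodendrocytes were lower in cortex libraries labelled CD51+. The microglial adaptor gene Tyrobp was at 1.63 ± 0.831 CPM (SD, n = 3) against 385 ± 161, a log2 fold change of -7.87 ± 0.92 (SE; edgeR adjusted p = 1.98e-05), and the protease gene Ctss at 13.7 ± 13.5 against 714 ± 32.3 CPM. Of the 14 microglial markers 9 were lower (13 adjusted over the list alone; median -4.44), and camera gave adjusted p = 2.48e-13, and adjusted p = 0.0861 with an estimated correlation. Of 6 other leukocyte or macrophage markers 5 were lower (5 adjusted over the list alone), with a median of -9.24, or -7.91 with genes at 0 counts placed at their bound (camera adjusted p = 5.51e-05, and adjusted p = 0.0547 with an estimated correlation). Mrc1, the macrophage mannose receptor, had 1 count in CD51+ against 61.2 ± 3.73 CPM, a ratio of 1130 (95% counting interval 203 to 44700). Myelin genes were lower in 6 of 13 cases (9 adjusted over the list alone; median -4.01), with the myelin basic protein gene Mbp at 2070 ± 372 against 33300 ± 15200 CPM and Ermn at 0.697 ± 0.711 against 224 ± 164 CPM. The myelin list had a camera adjusted p of 7.49e-07, and adjusted p = 0.122 with an estimated correlation. Limma-voom ended the call of Mbp (adjusted p = 0.929) and called 3 of the 13 myelin genes, against 6 in edgeR. Neuronal markers had a median of 0.38, and their edgeR calls numbered 0 of 10 (0 at an unadjusted p under 0.05, 0 with DESeq2 and 0 with limma-voom; camera adjusted p = 0.592). Interferon-response genes had a median of -2.69 with 1 of 11 lower (1 adjusted over the list alone), the class I light chain B2m at 260 ± 145 against 1390 ± 368 CPM. The interferon list had a camera adjusted p of 0.0227, and adjusted p = 0.122 with an estimated correlation. Ribosomal protein genes had a median of -1.27 with 3 of 36 lower (0 adjusted over the list alone), among them Rpl10 at 42.6 ± 31.3 against 283 ± 216 CPM. The ribosomal list had a camera adjusted p of 0.000402, and adjusted p = 0.22 with an estimated correlation. The edgeR call of B2m ended without cortex CD51+ replicate 3 (adjusted p = 0.0501). That of Rpl10 ended in edgeR without the same library (adjusted p = 0.106), without CD51− replicate 1 (0.148) or with only the cortex libraries (0.0573). The camera call of the interferon list ended without cortex CD51+ replicate 1 (adjusted p = 0.0527) or replicate 2 (0.0852).

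In total 1428 of 12613 tested genes differed in cortex in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 637 higher and 791 lower in CD51+. The genes named first by the rule were seen in 1 class only. Among genes with no count in CD51−, the synaptic adhesion gene Lrrc4b (150 ± 191 CPM in CD51+; SD, n = 3) was at least 1600-fold higher, the zinc finger gene Zfp423 at least 931-fold, the ciliary gene Dzip1l at least 855-fold, Sema3e at least 851-fold and Mlst8 at least 562-fold. Among genes with no count in CD51+, the ribonuclease gene Zc3h12a (191 ± 321 CPM in CD51−) was at least 1100-fold lower, the leukocyte receptor Slamf1 at least 716-fold, Pik3ap1 at least 543-fold, Rcsd1 at least 512-fold and the NF-kappa-B inhibitor gene Nfkbid at least 420-fold. Such folds and the ratios divide counts pooled over a group by its pooled TMM-scaled library sizes, so they can lie above or below the ratio of the mean CPM. The folds set 3 counts over the group as the floor and, as all floors and counting intervals here, cover counting error only, since PCR reads without molecular identifiers are not independent molecules. The spread between replicates was wide: of genes that reached 50 CPM in a library of the group, 6.98% in cortex CD51+ and 12.3% in cortex CD51− were under 1 CPM in another library of it. DESeq2 called 3219 genes and limma-voom 2164, and leaving out cortex CD51+ replicate 1, 2 or 3 left 935, 930 or 879 calls. The higher genes numbered 1472 with DESeq2, 1079 with limma-voom and 408 with only the cortex libraries, and 391 and 372 without cortex CD51+ replicate 3 and CD51− replicate 2. The lower genes numbered 1747 with DESeq2, and 476, 504 and 488 without cortex CD51+ replicates 1, 2 and 3. Without single libraries the calls of Sema3e (cortex CD51+ replicate 2, adjusted p = 0.148), Mlst8 (CD51+ replicate 3, 0.0529), Zc3h12a (CD51− replicate 2, 0.0983) and Slamf1 (CD51− replicate 2, 0.0595) ended in the edgeR test.

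**Figure D2:**
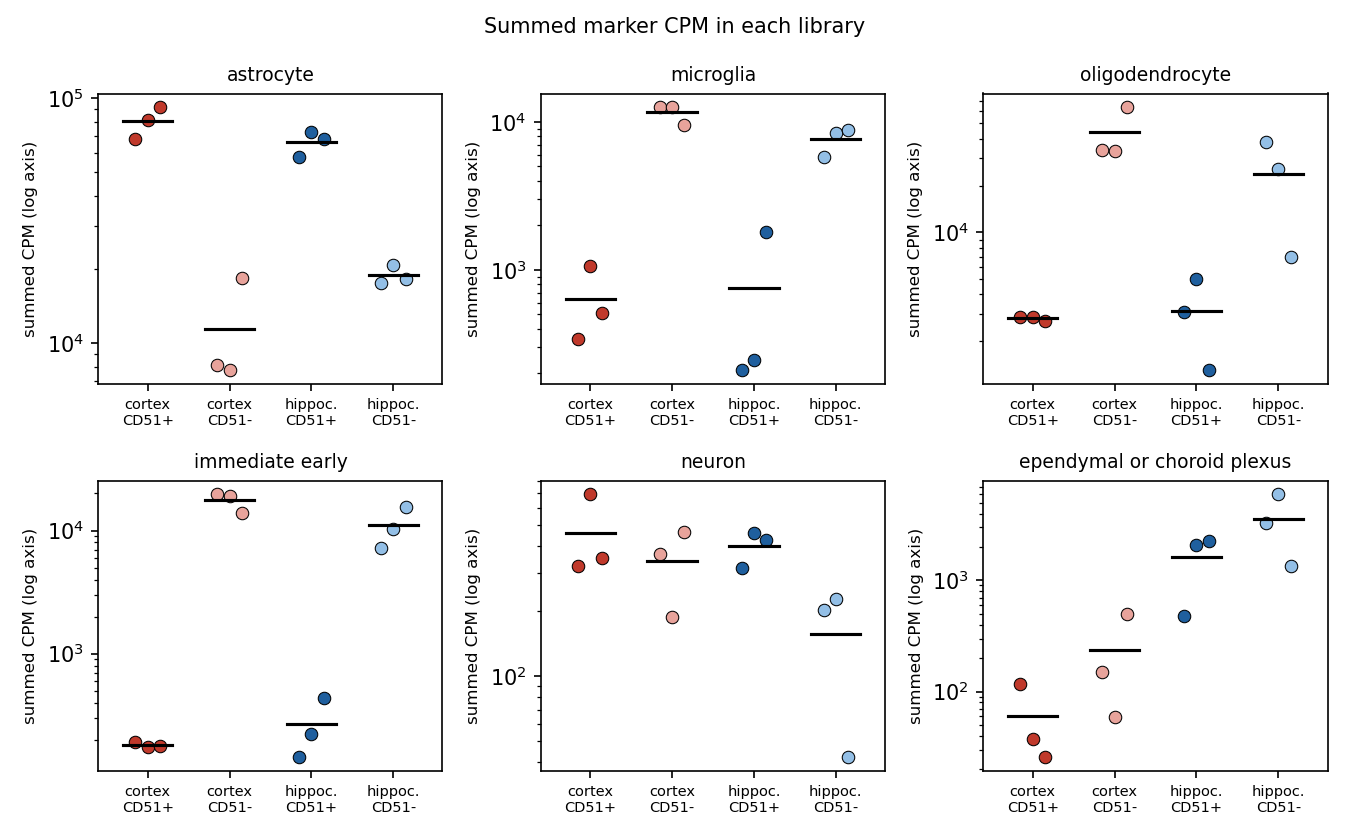
Summed TMM-scaled CPM of 6 marker lists in each library, on log axes, with 3 points and a line at the mean for each labelled group. Microglial markers average 638 in cortex CD51+ and 11630 in cortex CD51−, immediate early genes 181 and 17550, and neuronal markers 457 and 339.

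The second comparison asked the same of the hippocampal libraries. Astrocyte genes were again higher in the libraries labelled CD51+. Slc1a2 was at 32900 ± 3040 CPM (SD, n = 3) against 9710 ± 435, a log2 fold change of 1.76 ± 0.37 (SE; edgeR adjusted p = 0.00732), and Sparcl1 at 11200 ± 2150 against 2300 ± 361 CPM. In these libraries the microglial markers summed to 750 ± 906 CPM (SD, n = 3) in CD51+ and 7636 ± 1620 in CD51−, the oligodendrocyte markers to 3143 ± 1870 and 23550 ± 15700, and the pan-astrocyte markers to 66180 ± 7850 and 18900 ± 1730. The microglial sums of the CD51+ libraries were 209, 244 and 1795 CPM, so that replicate 3 carries their mean. The oligodendrocyte sums were 3081, 5041 and 1305 CPM in CD51+ and 38170, 25510 and 6974 CPM in CD51−. Of 20 pan-astrocyte markers 10 were higher (17 adjusted over the list alone; median 2.01; camera adjusted p = 2.78e-13, and adjusted p = 0.0527 with an estimated correlation). Synapse-organising factors were higher in 3 of 17 cases (3 adjusted over the list alone; median 1.75; camera adjusted p = 6.3e-05, and adjusted p = 0.0527 with an estimated correlation), and upper-layer and protoplasmic markers in 2 of 10 (5 adjusted over the list alone; median 2.27; camera adjusted p = 0.000186, and adjusted p = 0.0875 with an estimated correlation). Neurotransmitter genes were higher in 5 of 24 cases (11 adjusted over the list alone; median 1.74; camera adjusted p = 7.02e-08, and adjusted p = 0.0315 with an estimated correlation). Ion channel, water and calcium genes were higher in 5 of 24 (8 adjusted over the list alone; median 1.68; camera adjusted p = 7.02e-05, and adjusted p = 0.0432 with an estimated correlation). Limma-voom ended the call of Slc1a2 (adjusted p = 0.417) but called 14 of the 20 pan-astrocyte markers, against 10 in edgeR.

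Mitochondrial transcripts were higher in hippocampus libraries labelled CD51+, where mt-Nd2 was at 147000 ± 20000 CPM (SD, n = 3) against 38800 ± 10800 and mt-Nd5 at 92200 ± 27600 against 25900 ± 6490. Of the 13 mitochondrially encoded mRNAs 6 were higher (12 adjusted over the list alone; median log2 fold change 1.70; camera adjusted p = 8.22e-08, and adjusted p = 0.187 with an estimated correlation). Limma-voom ended both calls, with adjusted p = 0.0522 for mt-Nd2 and 0.961 for mt-Nd5. 

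Lists of metabolism and signalling in hippocampus had few single calls, and none of their medians exceeded that of the pan-astrocyte markers there. Cholesterol genes had a median of 1.31 (camera adjusted p = 0.000941, and adjusted p = 0.032 with an estimated correlation), with edgeR calls for 0 of 24 members (0 adjusted over the list alone, 4 at an unadjusted p under 0.05, 2 with DESeq2 and 2 with limma-voom). Apoe was at 2520 ± 450 against 833 ± 334 CPM (edgeR adjusted p = 0.0819). Notch, hedgehog, BMP and Wnt genes had a median of 1.41 (camera adjusted p = 0.000158, and adjusted p = 0.0315 with an estimated correlation), with 0 of 22 called in edgeR (0 adjusted over the list alone, 6 at an unadjusted p under 0.05, 1 with DESeq2 and 1 with limma-voom). Camera also placed 4 further lists above other genes, none of which passed with an estimated correlation. Fry, a test of a list against no change, gave them adjusted p-values of 0.0762 (patterning), 0.0583 (oxidative phosphorylation), 0.202 (matrix) and 0.121 (glycolysis). Patterning factors had a median of 1.03 (camera adjusted p = 0.0104, and adjusted p = 0.253 with an estimated correlation) with 0 of 18 called in edgeR (1 adjusted over the list alone, 4 at an unadjusted p under 0.05, 1 with DESeq2 and 3 with limma-voom). Nuclear oxidative phosphorylation genes had a median of 0.65 (camera adjusted p = 0.0111, and adjusted p = 0.165 with an estimated correlation) with 0 of 29 called in edgeR (0 adjusted over the list alone, 1 at an unadjusted p under 0.05, 1 with DESeq2 and 1 with limma-voom). Matrix genes had a median of 0.98 with 1 of 21 higher (3 adjusted over the list alone; camera adjusted p = 0.0329, and adjusted p = 0.289 with an estimated correlation). Glycolysis genes had a median of 0.55 with 1 higher and 1 lower of 23 (2 and 1 adjusted over the list alone; camera adjusted p = 0.0338, and adjusted p = 0.279 with an estimated correlation). The perineuronal proteoglycan gene Ncan was at 2640 ± 506 against 508 ± 82.7 CPM (edgeR adjusted p = 0.0194), the patterning factor Zbtb20 at 2560 ± 902 against 829 ± 297 CPM (adjusted p = 0.0659), and Aldoc at 4930 ± 941 against 1140 ± 226 CPM (adjusted p = 0.0179). Without hippocampus CD51+ replicate 2 the edgeR calls of Ncan (adjusted p = 0.0575; 0.051 without CD51− replicate 1) and Aldoc (0.0575) ended. The camera calls of 3 lists ended too: the matrix list (adjusted p = 0.0506; 0.0585 and 0.0971 without CD51− replicates 2 and 3), the glycolysis list (0.134; 0.0626 without CD51+ replicate 3, 0.127 and 0.0882 without CD51− replicates 1 and 2) and the patterning list (0.0506).

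Immediate early, microglial and other leukocyte genes were lower in hippocampus libraries labelled CD51+. Egr1 was at 99.7 ± 44.2 CPM (SD, n = 3) against 4280 ± 1850, a log2 fold change of -5.42 ± 0.59 (SE; edgeR adjusted p = 6.92e-06), and Atf3 at 1.61 ± 1.54 against 829 ± 158 CPM. Egr3 had 2 counts in CD51+ against 150 ± 66.4 CPM, a ratio of 1320 (95% counting interval 366 to 10900). Of 19 immediate early genes 14 were lower (18 adjusted over the list alone), with a median log2 fold change of -5.83, or -5.78 with genes at 0 counts at their bound (camera adjusted p = 1.56e-29, and adjusted p = 0.00395 with an estimated correlation). Tyrobp was at 9 ± 5.54 against 242 ± 24.7 CPM and the purine receptor P2ry12 at 177 ± 199 against 1600 ± 389 CPM, and 7 of 14 microglial markers were lower (12 adjusted over the list alone; median -3.39; camera adjusted p = 9.89e-14, and adjusted p = 0.0527 with an estimated correlation). Of 6 other leukocyte or macrophage markers 4 were lower (6 adjusted over the list alone; median -9.50, or -7.31 with genes at 0 counts at their bound; camera adjusted p = 5.34e-07, and adjusted p = 0.0451 with an estimated correlation). The TGF-beta receptor Tgfbr1 was at 7.39 ± 2.31 against 488 ± 69.7 CPM (edgeR adjusted p = 3.31e-05). Myelin genes had a median of -1.78 with 2 of 13 lower (4 adjusted over the list alone; camera adjusted p = 0.0566 in the edgeR fit), Mbp at 1950 ± 1250 against 18100 ± 11500 CPM. Reactive astrocyte genes had a median of -4.57 with 3 of 22 lower (8 adjusted over the list alone; camera adjusted p = 0.000277, and adjusted p = 0.0527 with an estimated correlation). Their lowest p belonged to Cd14, a receptor of myeloid cells, at 0.274 ± 0.365 against 62.9 ± 27.2 CPM (edgeR adjusted p = 0.00817; 0.0546 without hippocampus CD51+ replicate 2). Limma-voom ended the calls of Egr1 (adjusted p = 0.143) and Mbp (0.961), and the myelin list was called without hippocampus CD51+ replicate 2 (camera adjusted p = 0.01) or CD51− replicate 3 (0.00166).

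In total 418 of 12613 genes differed in hippocampus in the edgeR test, 78 higher and 340 lower in CD51+. With no count in CD51−, the protocadherin Pcdhb7 (33.5 ± 50.2 CPM in CD51+; SD, n = 3) was at least 464-fold higher, the ciliary gene Evc2 at least 445-fold, the actin-related gene Actr3b at least 381-fold and the neuronal migration gene Astn2 at least 198-fold. Lrrc27 had 1 count in CD51− against 55.8 ± 84.5 CPM, a ratio of 2320 (95% counting interval 415 to 91600). With no count in CD51+, the granulocyte colony-stimulating factor receptor Csf3r (101 ± 85.8 CPM in CD51−) was at least 588-fold lower, the inflammasome adaptor Pycard at least 559-fold, Nfkbid at least 553-fold, the urokinase gene Plau at least 503-fold and the immediate early gene Egr2 at least 493-fold. In hippocampus 4.79% of CD51+ and 5.72% of CD51− genes that reached 50 CPM in a library were under 1 CPM in another of the group. DESeq2 called 1457 genes, limma-voom 885 and the unfiltered edgeR test 636, and leaving out hippocampus CD51+ replicate 1 or 2 left 269 or 198 calls. The higher genes numbered 387 with DESeq2, 258 with limma-voom, 168 with only the hippocampus libraries and 119 with a replicate block within each stratum. They numbered 29 and 40 without hippocampus CD51+ replicates 2 and 3, and 37, 27 and 33 without CD51− replicates 1, 2 and 3. The lower genes numbered 1070 with DESeq2, 627 with limma-voom and 531 without the low-count filter, and 210 and 169 without hippocampus CD51+ replicates 1 and 2. The edgeR calls of these 5 higher genes ended without hippocampus CD51+ replicate 2, with adjusted p-values of 0.13 for Pcdhb7, 0.235 for Evc2, 0.0582 for Actr3b, 0.0623 for Astn2 and 0.307 for Lrrc27, and without single CD51− libraries, with 0.051 to 0.124 (Astn2 also without CD51+ replicate 1, 0.0573). Evc2 lost its call in 5 of 18 alternatives, of which 4 were left-out libraries.

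The mean of the regional differences was tested next, over 6 against 6 libraries. A strong change in 1 region alone can also be called by this test, so its calls need not be shared by both regions. Averaged in this way, 2868 of 12613 genes differed in the edgeR test, 1119 higher and 1749 lower in CD51+. With no count in any of the 6 CD51− libraries, Pcdhb7 (39.7 ± 50.2 CPM; SD, n = 6) was at least 798-fold higher, Actr3b at least 680-fold, the glycosyltransferase Gcnt4 at least 501-fold, Fam69c at least 442-fold and the receptor signalling inhibitor Spry4 at least 432-fold. With no count in any of the 6 CD51+ libraries, Zc3h12a was at least 1050-fold lower, Nfkbid (85.8 ± 59.8 CPM in CD51−) at least 995-fold, the transcription factor Klf2 at least 806-fold and Abi3 at least 756-fold, while Egr2 had 1 count, a ratio of 4230 (95% counting interval 759 to 167000). All 10 of these calls held in every alternative run. On average 19 of 20 pan-astrocyte markers were higher (20 adjusted over the list alone; median log2 fold change 2.48) and 13 of 14 microglial (14 adjusted over the list alone; median -3.94), 17 of 19 immediate early (18 adjusted over the list alone; median -6.64) and 6 of 6 other leukocyte markers (6 adjusted over the list alone; median -8.04, or -7.83 with genes at 0 counts at their bound) were lower. Camera gave adjusted p = 4.3e-16, 9.76e-16, 1.97e-30 and 1.18e-06 for these 4 lists, and adjusted p = 0.0332, 0.0426, 0.00595 and 0.0306 with an estimated correlation.

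Genes called in both regions moved the same way. Of the 637 higher genes in cortex and 78 in hippocampus, 57 were shared, where independent lists would share 3.94. Of the 791 and 340 lower genes, 286 were shared, where independent lists would share 21.3, and 0 genes were called in opposite directions by edgeR. Across genes, which are not independent replicates, the log2 fold changes of the 2 regions had a Pearson correlation of 0.48 and a Spearman correlation of 0.46. Of all 12613 tested genes, 66.5% had the same sign in both regions. Of the genes called in cortex, 90.9% had the same sign in hippocampus, and of those called in hippocampus, 98.6% had the same sign in cortex. The shared higher genes numbered 198 and the shared lower genes 742 with DESeq2. Without hippocampus CD51+ replicate 2 the shared genes numbered 18 and 151, and without hippocampus CD51+ replicate 1 the shared lower genes numbered 184. Without CD51+ replicate 3 or CD51− replicate 1, 2 or 3 of hippocampus the shared higher genes numbered 24, 22, 19 and 24.

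**Figure D3:**
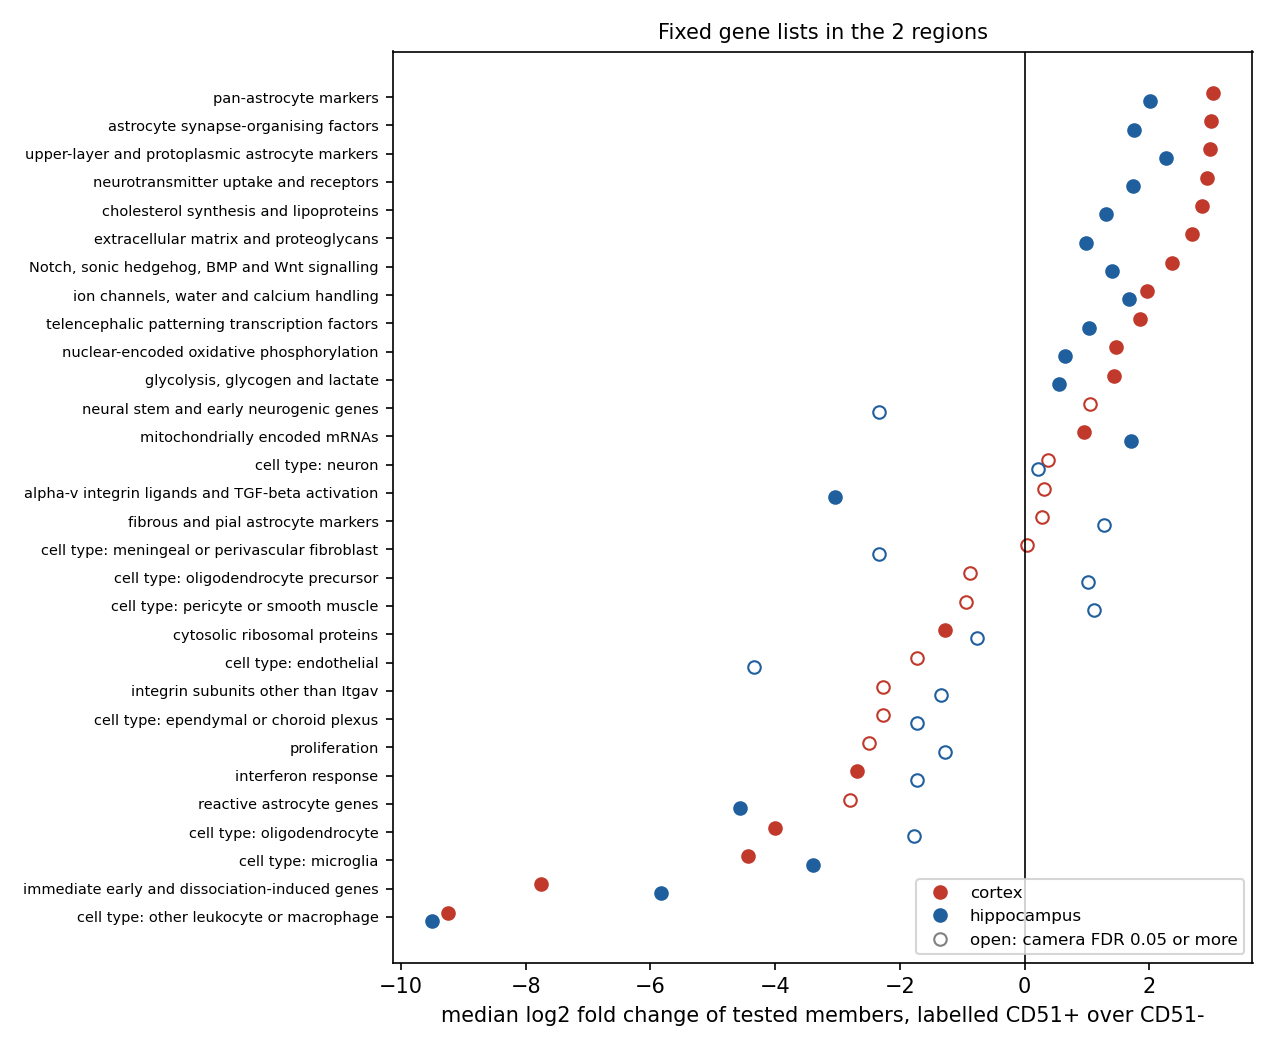
Median log2 fold change of the tested members of each fixed gene list, labelled CD51+ over CD51−, in cortex (red) and hippocampus (blue), with filled points where the camera adjusted p is under 0.05. Pan-astrocyte markers lie at 3.03 and 2.01, and immediate early genes at -7.75 and -5.83.

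Whether the CD51 difference itself depends on the region was tested as an interaction. Egr1 differed by -7.75 in cortex and -5.42 in hippocampus on the log2 scale (interaction 2.32 ± 0.70, SE; edgeR adjusted p = 0.17), and Slc1a2 by 3.13 and 1.76 (interaction -1.37 ± 0.51; adjusted p = 0.264). The edgeR test called 0 of 12613 genes, with 1583 at an unadjusted p under 0.05, while DESeq2 called 522, limma-voom 0 and the unfiltered edgeR test 146. Calls by edgeR numbered 42 without cortex CD51− replicate 3, 3 without cortex CD51+ replicate 1, 3 without hippocampus CD51+ replicate 1, 2 without hippocampus CD51+ replicate 3 and 1 without each of cortex CD51− replicates 1 and 2 and hippocampus CD51− replicate 3. At gene level the reach for such a difference was small in simulated data of 12613 genes, drawn from the model that edgeR fits. There edgeR recovered 6% of interaction changes of 4 log2 units and 44% of changes of 8.

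The third comparison asked how the hippocampal libraries differ from the cortical ones, averaged over the labelled classes. Whether a difference lies in astrocytes or in the mix of sorted cells was not tested. Genes of the choroid plexus and ependyma, the epithelia of the ventricles, were higher in hippocampus. The transthyretin gene Ttr, a major choroid plexus product (ENSMUSG00000061808.4, chromosome 18, 20665280 to 20674321), was at 2260 ± 1700 CPM (SD, n = 6) in hippocampus against 106 ± 162 in cortex, a log2 fold change of 4.70 ± 0.74 (SE; edgeR adjusted p = 0.00684). The prolactin receptor gene Prlr was at 112 ± 88.4 against 13.2 ± 20.6 CPM. Of the 10 tested ependymal or choroid plexus markers 4 were higher (8 adjusted over the list alone), with a median log2 fold change of 6.55 (camera adjusted p = 1.56e-11, and adjusted p = 0.0499 with an estimated correlation). Summed, these markers reached 1610 ± 984 CPM (SD, n = 3) in hippocampus CD51+ and 3558 ± 2360 in hippocampus CD51−, against 60 ± 49.6 and 237 ± 233 in the cortex groups. Cortex CD51+ replicate 1 (117 CPM, against 37.5 and 25.6) and cortex CD51− replicate 3 (501 CPM, against 151 and 59) were the highest of their groups. Among the named genes with the largest difference, the axonemal gene Rsph4a (41.9 ± 32 CPM; SD, n = 6) had no count in cortex and was at least 770-fold higher, the guidance gene Slit2 had 1 count in cortex against 56.7 ± 43.7 CPM (ratio 2250, 95% counting interval 403 to 88900). With no count in cortex, the collagen gene Col8a1 was at least 803-fold higher and the bicarbonate transporter Slc4a5 at least 263-fold higher. Limma-voom and the robust edgeR fit ended the call of Ttr (adjusted p = 0.214 and 0.0812). That of Slc4a5 ended in edgeR without cortex CD51+ replicate 1 (adjusted p = 0.0603), 2 (0.0756) or 3 (0.0877), cortex CD51− replicate 1 (0.0566) or 2 (0.0519), hippocampus CD51+ replicate 3 (0.0515) or hippocampus CD51− replicate 2 (0.0799).

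Fibrous and pial astrocyte markers had a median of 2.52 in hippocampus over cortex (camera adjusted p = 0.000401, and adjusted p = 0.0499 with an estimated correlation). Of 9 members 0 were called in edgeR (3 adjusted over the list alone, 5 at an unadjusted p under 0.05, 3 with DESeq2 and 0 with limma-voom). The intermediate filament gene Gfap was at 187 ± 128 CPM (SD, n = 6) against 48.2 ± 93.5 (edgeR adjusted p = 0.0746). Telencephalic patterning factors had a median of 1.08 (camera adjusted p = 7.18e-05, and adjusted p = 0.202 with an estimated correlation), and their lowest p was that of Zic1, at 20.2 ± 26.1 against 0.661 ± 1.05 CPM (edgeR adjusted p = 0.0844). Of these 18 factors 0 were called in edgeR (5 adjusted over the list alone, 7 at an unadjusted p under 0.05, 4 with DESeq2 and 1 with limma-voom). Neuronal markers had a median of -1.16 (camera adjusted p = 0.0414, and adjusted p = 0.612 with an estimated correlation). Their edgeR calls numbered 0 of 10 (0 adjusted over the list alone, 2 at an unadjusted p under 0.05, 0 with DESeq2 and 0 with limma-voom). The camera call of this list ended with a replicate block (adjusted p = 0.0662), with mitochondrial genes left out (0.134), and without cortex CD51+ replicate 1 (0.158) or 2 (0.0542), cortex CD51− replicate 1 (0.0672) or 3 (0.188), hippocampus CD51+ replicate 2 (0.0509) or 3 (0.0636) or hippocampus CD51− replicate 3 (0.177). Fry, against no change, gave the list adjusted p = 0.291. Pan-astrocyte markers had a median of 0.11, with 0 of 20 called in edgeR (0 at an unadjusted p under 0.05, 0 with DESeq2 and 0 with limma-voom; camera adjusted p = 0.83). 

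In total 24 of 12613 genes differed between the regions in the edgeR test, 20 higher and 4 lower in hippocampus. The lower ones were the BMP antagonist Chrdl1 (19.4 ± 16.5 against 342 ± 288 CPM), the transcription factor Runx1 (35.6 ± 43.8 against 110 ± 122 CPM), Csf3r and Zfp629, of which Csf3r and Zfp629 were picked out after their values were seen. Limma-voom ended the calls of Chrdl1 (adjusted p = 0.0537) and Runx1 (0.148). The edgeR call of Runx1 also ended with upper-quartile scaling (adjusted p = 0.0519), with a replicate block (0.0586), and without cortex CD51+ replicate 1 (0.0923), hippocampus CD51+ replicate 2 (0.0677) or 3 (0.0647) or hippocampus CD51− replicate 2 (0.0805). DESeq2 called 723 genes, limma-voom 53, the unfiltered edgeR test 292 and the robust edgeR fit 112, and leaving out cortex CD51− replicate 3, hippocampus CD51+ replicate 1, hippocampus CD51− replicate 2 or hippocampus CD51− replicate 3 gave 69, 41, 11 or 59. With single libraries left out, the 20 higher genes became 9 to 50 and the 4 lower genes 2 to 19.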

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

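The 4 differences below are interaction tests of lists fixed before the data were examined, and no test in this part was chosen after its result was seen except the settings with mitochondrial genes left out, upper-quartile scaling of lists and left-out libraries.

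A difference between the regions in the CD51 contrast was seen for 4 lists with camera. Myelin genes had an interaction median of 2.73 (camera adjusted p = 2.54e-05, and adjusted p = 0.6 with an estimated correlation), with medians of -4.01 in cortex and -1.78 in hippocampus, where the list was not called (camera adjusted p = 0.0566, and adjusted p = 0.457 with an estimated correlation). The hippocampus CD51− libraries summed to 38170, 25510 and 6974 CPM for these markers. Mbp was at 2070 and 33300 CPM in cortex CD51+ and CD51− and at 1950 and 18100 CPM in hippocampus (n = 3 each). Cholesterol genes had an interaction median of -1.65 (camera adjusted p = 0.00391, and adjusted p = 0.11 with an estimated correlation), with medians of 2.85 in cortex and 1.31 in hippocampus. Nsdhl, a sterol dehydrogenase gene, was at 46.3 and 0 CPM in cortex and 15.6 and 26.9 CPM in hippocampus (edgeR adjusted p = 0.139). Pan-astrocyte genes had an interaction median of -0.88 (camera adjusted p = 0.0498, and adjusted p = 0.6 with an estimated correlation), and ribosomal genes 0.68 (camera adjusted p = 0.0498, and adjusted p = 0.6 with an estimated correlation). The camera call of the pan-astrocyte list ended with RLE factors (adjusted p = 0.0535), upper-quartile scaling (0.0547) and mitochondrial genes left out (0.0505), and without cortex CD51+ replicate 3 (0.114), cortex CD51− replicate 1 (0.204) or 2 (0.081), hippocampus CD51+ replicate 1 (0.0912) or 3 (0.0503) or hippocampus CD51− replicate 1 (0.0605) or 2 (0.0628). That of the ribosomal list ended in camera with mitochondrial genes left out (adjusted p = 0.0505), and without cortex CD51+ replicate 1 (0.0688) or 3 (0.134), cortex CD51− replicate 1 (0.0766) or 2 (0.081), hippocampus CD51+ replicate 3 (0.29) or hippocampus CD51− replicate 1 (0.0649) or 3 (0.144). The camera calls of the myelin and cholesterol lists ended only with the estimated correlation. Fry tests a list against no change rather than against other genes, and gave adjusted p = 0.206 for the myelin, 0.206 for the pan-astrocyte, 0.359 for the ribosomal and 0.00298 for the cholesterol list. No single member of these lists was called by edgeR for the interaction, and no biological explanation was tested.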

How the results depend on the processing

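Fits with mitochondrial genes left out and left-out libraries for lists and shared calls were chosen after the data were seen. Changes of direction were counted only for lists and named genes called in the main fit or in the alternative compared. Among these no list changed direction, and only 1 gene lost its direction. Sign changes without a call were not counted. The Otx2 log2 fold change, cortex libraries left out singly, ran from -9.31 to 0.00, the last without cortex CD51− replicate 3, which held its only cortex counts. The cause was not tested for any change below. DESeq2 called 3219 genes in cortex, 1457 in hippocampus, 723 between regions and 522 for the interaction, with 198 shared higher and 742 shared lower. Limma-voom called 2164 in cortex, 885 in hippocampus and 53 between regions. Without the low-count filter edgeR called 636 in hippocampus, 292 between regions and 146 for the interaction. Robust dispersion gave 112 between regions and 1 for the interaction. Left-out single libraries gave 879 to 1507 in cortex, 198 to 363 in hippocampus, 11 to 69 between regions, 0 to 42 for the interaction, 18 to 85 shared higher and 151 to 349 shared lower, and 2 to 7 interaction lists. With an estimated correlation, 7 lists were called in cortex, 6 in hippocampus, 10 in the average, 2 between regions and 0 for the interaction, where fry called 1 and leaving out mitochondrial genes 2.

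With the replicate number as a block, 1260 genes were called in cortex, 435 in hippocampus, 2540 in the average, 28 between regions and 0 for the interaction. A block within each stratum gave 73 between regions and 7 for the interaction. No pairing of the samples by number was seen: libraries with the same number had a mean correlation of 0.003, and 4 of 12 correlated best with their own number. With few libraries per group and a wide spread between replicates, such values cannot exclude a pairing. Gene counts stayed within a fixed factor of the main count in 94 comparisons and moved beyond it in 39. That factor is wide, since 971 cortex calls without cortex CD51− replicate 2 lay within it, against 1428 in the main fit. Of calls of genes that the naming rule gives, some of them left out of the text, 42 of 58 held in every alternative in cortex, 13 of 37 in hippocampus, 10 of 10 in the average and 6 of 17 between regions. Depth limits genes with few counts, for which floors are given.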

Other observations

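The tests of the microglial and neuronal ratio, the microglial markers, the immediate early ratio and median and the Itgav title were chosen only after the result was seen. The dilution test and the splits were not.

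Genes linked to CD51 itself moved both ways, in libraries whose astrocyte and microglial markers also differed. Whether they changed within astrocytes or with the mix of cell types was not tested. Itgb8, whose protein pairs with integrin alpha-v and activates latent TGF-beta, was at 517 ± 166 CPM (SD, n = 3) in cortex CD51+ against 38.2 ± 16.9 in CD51− (edgeR adjusted p = 0.00139). The TGF-beta receptor Tgfbr1 was at 87.3 ± 47.6 against 629 ± 237 CPM (adjusted p = 0.00526 in edgeR) and the pathway inhibitor Smad7 had 3 counts in CD51+ against 103 ± 20.4 CPM, a ratio of 666 (95% counting interval 228 to 3230). The collagen receptor Itga1 was absent from cortex CD51+ and at 16.7 ± 14.7 CPM in CD51−, at least 88.6-fold lower. Its edgeR call ended without cortex CD51+ replicate 1 (adjusted p = 0.0886), 2 (0.0975) or 3 (0.0864) or CD51− replicate 2 (0.0686), with limma-voom (0.0903) and with replicate blocks (0.0502, and 0.0704 within each stratum). In cortex integrins had a median of -2.27 with 1 higher and 2 lower of 11 (2 and 5 adjusted over the list alone; camera adjusted p = 0.144), and alpha-v ligands and TGF-beta genes 0.32 with 1 higher and 5 lower of 19 (3 and 6 adjusted over the list alone; camera adjusted p = 0.275). In hippocampus the fibronectin receptor Itga5 was absent from CD51+ and at 28.9 ± 15 CPM in CD51−, at least 172-fold lower (edgeR adjusted p = 0.0291). The call ended without hippocampus CD51+ replicate 1 (adjusted p = 0.0797), 2 (0.102) or 3 (0.082). There integrins had a median of -1.34 with 1 of 11 lower (1 adjusted over the list alone; camera adjusted p = 0.288), and alpha-v ligands and TGF-beta genes -3.04, or -2.24 with genes at 0 counts at their bound, with 2 of 19 lower (5 adjusted over the list alone; camera adjusted p = 0.0101, and adjusted p = 0.0527 with an estimated correlation). That camera call ended without hippocampus CD51+ replicate 1 (adjusted p = 0.0543).

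Reactive genes in cortex had a median of -2.80, or -2.22 with genes at 0 counts at their bound, with 2 higher and 7 lower of 22 (4 and 8 adjusted over the list alone; camera adjusted p = 0.0721). Cd14 had 1 count in cortex CD51+ against 62.5 ± 38.4 CPM (SD, n = 3), a ratio of 1270 (95% counting interval 228 to 50300). Fibrous and pial markers had a median of 0.28 in cortex (camera adjusted p = 0.275) and 1.27 in hippocampus (0.306), neural stem genes 1.05 (0.144) and -2.33 (0.637), and proliferation genes -2.50, or -0.86 at the bound (0.275), and -1.27 (0.293). In cortex Gfap, the filament gene of reactive astrocytes, was at 93.4 ± 125 against 3.02 ± 3.92 CPM (edgeR adjusted p = 0.00983; 0.0842 without cortex CD51+ replicate 3, 0.0795 with limma-voom, 0.0591 with only the cortex libraries), and the stem cell factor Sox2 at 72.6 ± 40.8 against 0.582 ± 0.759 CPM (edgeR adjusted p = 0.00388). In hippocampus interferon genes had a median of -1.73 (camera adjusted p = 0.139), ribosomal genes -0.76 (0.0803) and neuronal markers 0.22 (0.23). Endothelial markers had medians of -1.73 in cortex (camera adjusted p = 0.289) and -4.34, or -2.45 at the bound, in hippocampus (0.106), pericyte markers -0.94 (0.289) and 1.11 (0.428), fibroblast markers 0.04 (0.924) and -2.33 (0.428), oligodendrocyte precursor markers -0.87 (0.494) and 1.02 (0.23), and ependymal markers -2.27, or -0.67 at the bound (0.156), and -1.73 (0.213). Single members of these lists were called by edgeR in cortex. Olig2, a factor of the oligodendrocyte lineage, was higher, at 61.7 ± 27 CPM against 1 count in CD51−, a ratio of 1590 (95% counting interval 285 to 63000; adjusted p = 0.00263), as 1 of 4 precursor markers. The receptor gene Pdgfrb, a pericyte marker, was higher, at 36.2 ± 16.1 CPM against no count, at least 319-fold (edgeR adjusted p = 0.00351), as 1 of 6 pericyte markers. Of 10 ependymal markers 3 were lower (3 adjusted over the list alone), Prlr at least 165-fold, with no count in CD51+ against 26.5 ± 23.2 CPM, and Kl and Otx2, with no count against 22.1 ± 29.2 and 6.71 ± 11.6 CPM. The edgeR call of Otx2 ended with upper-quartile scaling (adjusted p = 0.0527) and replicate blocks (0.144 and 0.132), with limma-voom (0.606), without cortex CD51+ replicate 1 (0.0949), 2 (0.108) or 3 (0.0996), and without cortex CD51− replicate 3 (1). Neural stem genes were higher in 2 of 13 cases, Sox2 and the growth factor receptor Egfr (4 higher and 1 lower adjusted over the list alone; Egfr edgeR adjusted p = 0.0105, and 0.0942 without cortex CD51+ replicate 3), and fibrous and pial markers in 1 of 9 (2 higher and 1 lower adjusted over the list alone). The female transcript Xist was at 375 to 1130 CPM in the CD51+ libraries and 1320 to 3570 in the CD51− libraries. Its edgeR adjusted p was 0.0513 in cortex, where 6 alternatives called it (0.00911 without cortex CD51− replicate 3, and 0.0137 to 0.0469 with 5 other settings), and 0.044 in hippocampus, where the call ended without CD51+ replicate 2 (0.17) or 3 (0.183) or CD51− replicate 2 (0.0863) or 3 (0.145), and with DESeq2 (0.0685), limma-voom (0.0709), RLE factors (0.0573) and upper-quartile scaling (0.094). In cortex CD51− replicate 3 the Y-linked Ddx3y was at 56.7 CPM and Uty at 47.7, and Ddx3y was at 19.8 in cortex CD51+ replicate 2 and 0 in all hippocampus libraries.

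Hypotheses for the first pattern, microglial genes higher and astrocyte genes lower in libraries labelled CD51−, were weighed against each other. Microglia in the sorted fraction stay open: 28 of 28 pairs of microglial marker and region were higher in CD51−, which restates the pattern and does not test its source. A lower astrocyte share that raises every other cell type alike is argued against only as far as neuronal markers go. The ratio of microglial to neuronal sums was 1.06 to 1.52 in cortex CD51+ and 20.7 to 67.4 in cortex CD51−, and 0.53 to 4.22 against 28.6 to 208 in hippocampus (exact stratified permutation p = 0.005, n = 6 against 6). Its numerator is part of the pattern, and the neuronal sums were low. Oligodendrocyte sums were also higher in CD51− in both regions, so a shared rise of microglia and oligodendrocytes stays open. Dilution of otherwise equal astrocytes stays open: scaled to the pan-astrocyte sum, 193 of 12613 genes were called higher in CD51+ by edgeR in the average over regions (1.53%, between the bounds of 1% and 5%) and 5494 lower, with 133 higher (1.05%) and 4260 lower in cortex and 6 higher (0.0476%) and 1564 lower in hippocampus. A difference between CD51 classes of astrocytes remains among the open explanations, untested.

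A hypothesis for the second pattern, immediate early genes higher in libraries labelled CD51−, is that microglial RNA is the whole source. If microglial RNA had the same immediate early level in both fractions, the ratio of immediate early to microglial sums would overlap between the classes. It was 0.164 to 0.567 in cortex CD51+ and 1.45 to 1.57 in cortex CD51−. In hippocampus it was 0.245 to 0.918 against 1.22 to 1.79 (exact stratified permutation p = 0.005 over both regions, n = 6 against 6). These values argue against that narrower form only. The ratio was chosen after its parts were seen, and its numerator is the pattern itself. Microglia of the 2 fractions could differ in their own immediate early level. A difference in handling between the 2 sorted fractions cannot be told apart from the class, the list median being -6.64 in the average over regions. The CD51 class itself stays open, untested.

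A hypothesis for the third pattern is that titles were exchanged between the classes, since the library names read G for titles CD51+ and GT for titles CD51−, which could stand for GFP and for GFP with tdTomato. Itgav gives no answer, at a log2 fold change of 0.43 ± 0.39 (SE, n = 6 against 6) in CD51+, and the exchange stays open. If titles were exchanged, every CD51 difference here would change sign.

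Other groupings of the same libraries were counted. In cortex and in hippocampus 10 splits are too few for a share under 0.05: 1 of 10 called as many genes as the real split, with 1428 and 418 genes against at most 0 in any other. Averaged over regions 1 of 100 splits did, with 2868 genes and at most 404 in another, and between regions 1 of 100, with 24 genes and at most 2. For the interaction, with 0 genes, every split must call as many, so the 100 of 100 that did say nothing about chance. The highest other split called 2868, since exchanging the classes in 1 region turns the interaction into the average.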
